A study of Mus musculus with 2 samples.

How the data were processed

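Cells came from small-intestinal crypts after 5 daily injections of 1 mg tamoxifen, and the labels give 1 gene expression library made with droplet-based 3-prime chemistry (10x Genomics) and 1 hashtag antibody library. Per the labels, Cell Ranger and Seurat were used, without versions; the matrix header gives software version 3.1.0. The labels name a human genome build while the gene identifiers are mouse Ensembl identifiers plus YFP and tdTomato, so no coordinates are given. The deposited matrix holds raw counts of UMIs for 31055 genes and raw antibody counts for 4 hashtags over 11248 barcodes. The authors' filtered count table holds 2335 of these barcodes; 0 of its entries differed from the matrix, and its values are raw counts. The authors' normalised table was checked against the counts and holds the natural logarithm (ln) of 1 plus 10000 times the UMIs of a gene over the total UMIs of the cell. The deposited hashtag counts are raw as well. All sums started from the raw counts.

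The filter by which the authors kept 2335 barcodes is not stated. Kept cells had at least 1002 UMIs, 566 genes and 40 hashtag counts, and at most 12.5% mitochondrial UMIs. They held 51238250 of the 92424393 UMIs. Of the 8913 barcodes left out, 7451 lay above the highest mitochondrial percentage of the kept cells, and 937 lay within all 3 gene expression limits, with a median of 63 hashtag counts against 224 in kept cells. Left-out barcodes entered no comparison.

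A cell was assigned to a tag pair when its counts of that pair were at least 3 times those of the other. This and the choices below were made before the data were examined, except where stated. Counts were scaled to 10000 per cell and logged, 2000 variable genes and 30 principal components were taken, and cells were clustered on a graph of 15 neighbours by the Leiden method at resolution 1 (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, Python 3.11.15). A cluster was named by the marker list of which at least 3 genes were at least 0.5 higher in log2 and found in at least 10% of its cells. Lists that named a cluster covered stem-like, cycling, enterocyte-like, goblet-like, Paneth-like, enteroendocrine-like, enterochromaffin-like, peptide hormone enteroendocrine-like, tuft-like, T cell-like and B or plasma cell-like cells. Lists for early secretory and enteroendocrine progenitors, myeloid, stromal, endothelial and enteric neural cells named none of the 15 clusters. Of these, the enteroendocrine progenitor list had a median log2 ratio of 0.53, the early secretory list 0.40 and the myeloid list -1.36 over all cells of tags 1 and 2 against tags 3 and 4; 1 endothelial gene and 3 neural genes were measured, with medians of 0.34 and 0.11, and no stromal gene was. Clusters 2 and 10 stayed without a name, the latter holding 93 shallow cells with a median of 2081 UMIs. Cluster 2 had under 3 such genes of any list. Cluster 10 had 4 of the cycling list (Mki67, Top2a, Hmgb2 and Pcna). It was left unnamed because its cells were shallow and none of these 4 was among its leading genes.

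UMIs were summed per tag pair over all cells and within classes with at least 20 cells in each pair, and given as CPM, per 1000000 UMIs of the summed cells. Ratios are log2 with a pseudocount of 10 CPM. Sums carry exact 95% Poisson intervals and shares exact Clopper-Pearson intervals, whose upper bound is given for a share of 0; a sum of 0 UMIs is drawn at a limit of 3 counts. With 1 library shared by both pairs and no replicate, no p-value was computed and no gene was called changed. Over all cells, the 12 highest and 12 lowest ratios were named among genes with at least 50 UMIs, found in at least 5% of cells of the higher pair and with intervals apart. Mitochondrial genes and unnamed models were left out, and families of near-identical genes were limited to 3. The enteroendocrine-like class took 8 and 8 genes and other classes 5 and 5. Gene groups fixed in advance were enteroendocrine transcription factors, dense-core vesicle and exocytosis genes, hormone and amine synthesis genes, Notch pathway, reported reserve stem cell genes, fetal-like and regeneration genes, antimicrobial Reg3 genes, MHC class II, dissociation and stress genes and transgene transcripts. A member counts as measured with at least 20 UMIs and as above or below when the intervals were apart. Examples of a group are its members with most UMIs. Xist, the Y-linked genes as a set and the stem cell marker Lgr5 were chosen after their values were seen.

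For shares of cells with a UMI, each cell was thinned to 2000 UMIs and shallower cells were left out. No cell was removed as a doublet in the values reported first. The unassigned cells were left out by the tag rule and were not called doublets. Scrublet (in scanpy, expected rate 6%) marked 2 of 2335 cells by its own threshold, 0.0857%.

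The method was tested on simulated data drawn over 31055 genes. With 2-fold changes in 100 genes, 93% had intervals apart with the right sign, and with 4-fold changes in 100 genes, 100% did; 0.689% of 10889 unchanged genes had intervals apart. All 24 named genes were changed ones. The simulated cells of a pair shared 1 Poisson mean per gene and equal depth, without variation between cells. These shares therefore cover counting error only. They give no error rate for real cells, where single cells can hold most UMIs of a gene.

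Alternatives planned in advance were resolutions 0.5 and 2, 15 components, 4000 variable genes, clustering without a class's own markers, classes by marker share without clustering, at least 1000 genes and under 15% mitochondrial UMIs, doublets left out by Scrublet, a 10-fold tag rule, means over cells, thinning, and a total without mitochondrial genes and the 20 genes with most UMIs. Alternatives chosen after seeing the data were the split of the pairs at a log10 tag ratio of 0.5, which leaves no cell unassigned, clustering without YFP and tdTomato, cells with Xist and without Y-linked UMIs only, sums without the B, plasma and T cell-like clusters, leaving out the 6% of cells with the highest Scrublet scores, thinning to 10000 UMIs, and leaving out the 5 cells of each pair with most UMIs of a named gene, which is a larger share of the smaller pair. The last was also applied to stem- and cycling-like cells with and without YFP.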

Results

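Single-cell transcriptomes and hashtag antibody counts were collected from epithelial cells of mouse small-intestinal crypts. The labels name 1 mouse, which carried a tamoxifen-inducible Cre recombinase with tdTomato at Chga, the gene of the granule protein chromogranin A of enteroendocrine cells. A Rosa26 reporter expresses eYFP in cells after recombination and in their descendants. Tamoxifen was given as 5 daily injections of 1 mg. Cells sorted for eYFP and a bulk sort were stained with hashtag antibodies and pooled, so 1 gene expression library and 1 hashtag library hold both origins. The cells kept by the authors numbered 2335, with 1002 to 129719 unique transcript counts (UMIs) per cell, a median of 19078 and 51238250 in total. The map from hashtag to sort is not given in the sources used here, and the YFP level was not used to name a tag pair, so origins are called by their tag numbers. Both pairs share 1 library and neither has a replicate, so no test between pairs was made. Shares carry exact (Clopper-Pearson) 95% binomial intervals and summed UMIs exact 95% Poisson intervals, both of which cover counting error only.

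The question for the hashtag counts was which cells share an origin. The 4 tags acted as 2 pairs. Across cells, counts of tags 1 and 2 correlated with r = 0.959 and counts of tags 3 and 4 with r = 0.959, whereas tags from different pairs gave r from -0.585 to -0.509; cells are not independent replicates. Requiring at least 3 times the counts of the other pair assigned 987 cells to tags 1 and 2 (42.3%; median 16780 UMIs) and 411 cells to tags 3 and 4 (17.6%; median 18833 UMIs), and left 937 cells (40.1%; median 20481 UMIs) unassigned. Cells of tags 1 and 2 held a median of 235 counts of their own tags and 7 of the other pair. Cells of tags 3 and 4 held medians of 387 and 66. A split at the valley of the tag ratio, chosen after seeing the data, gave 981 and 1354 cells with none left unassigned, and a stricter 10-fold rule gave 907 and 120.

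**Figure D1:**
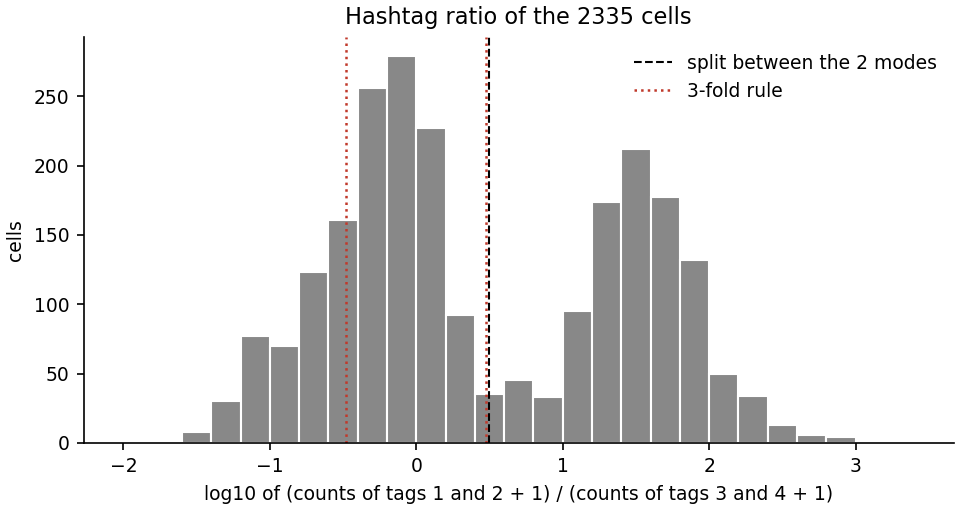
Number of cells (vertical axis) by the log10 ratio of the counts of tags 1 and 2 to those of tags 3 and 4, each with 1 added (horizontal axis), for 2335 cells. Dotted lines mark the 3-fold rule and the dashed line the split at 0.5 between the modes; 35 cells lie in the bin from 0.4 to 0.6, and 279 cells in the fullest bin, from -0.2 to 0.

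The first comparison asked which cell types make up each tag pair. Enteroendocrine-like cells, the hormone- and serotonin-producing cells of the epithelium, made up 37.2% of the cells of tags 1 and 2 (367 of 987; 34.2 to 40.3%) and 2.92% of those of tags 3 and 4 (12 of 411; 1.52 to 5.04%). Stem- and cycling-like cells were 31.2% (28.3 to 34.2%) against 44.0% (39.2 to 49.0%), and enterocyte-like cells 5.47% (4.14 to 7.08%) against 8.52% (6.003 to 11.6%). B or plasma cell-like cells were 0.405% (4 cells) against 20.4% (84 cells; 16.6 to 24.7%), and T cell-like cells 0.507% (5 cells) against 9.002% (37 cells; 6.42 to 12.2%). At the valley split these shares were 0.408% against 6.43% (87 cells) and 0.510% against 2.73% (37 cells). On the tags 3 and 4 side, the 3-fold rule kept 84 of 87 B or plasma cell-like cells. It kept 37 of 37 T cell-like cells there, but 181 of 645 stem- and cycling-like cells. Among the cells of named epithelial classes alone, the enteroendocrine-like share was 45.3% of 810 cells against 4.88% of 246 cells (2.55 to 8.37%). Over all cells of a pair, the enteroendocrine-like share was higher in tags 1 and 2 in 13 of 13 alternatives, by 6.28 to 22.0 times. The stem- and cycling-like share and the named epithelial classes leave out the unnamed cluster 2 (124 and 40 cells), described below. In its cells, Olfm4 was found in 99.2% and 97.5% and the cycling marker Mki67 in 68.5% and 77.5%.

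The intervals of the remaining secretory classes overlapped between the pairs. Mucus-producing goblet-like cells were 4.96% (3.70 to 6.51%) against 2.68% (1.34 to 4.74%). Paneth-like cells, which secrete antimicrobial defensins, were 2.23% (1.40 to 3.36%) against 1.70% (0.687 to 3.48%). Chemosensory tuft-like cells were 1.01% (10 cells; 0.487 to 1.86%) against 0 of 411 cells, for which the exact upper bound is 0.894%. Cluster 2, in which no marker list reached 3 genes and the DNA replication genes Cdt1, Ung, Mcm3 and Mcm6 led, was 12.6% (10.6 to 14.8%) against 9.73% (7.04 to 13.0%). With the split at the valley, the goblet-like share was 4.99% against 6.06% and the tuft-like share 1.02% against 1.26%, both lower in tags 1 and 2, and the enteroendocrine-like share of tags 3 and 4 was 5.91% (80 cells; 4.71 to 7.30%). Under the 10-fold rule, 49 of the 120 cells of tags 3 and 4 were B or plasma cell-like and 29 T cell-like; there the stem- and cycling-like share was 31.6% against 20%, the enterocyte-like share 5.51% against 3.33%, and the Paneth-like share 2.43% against 2.50%.

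**Figure D2:**
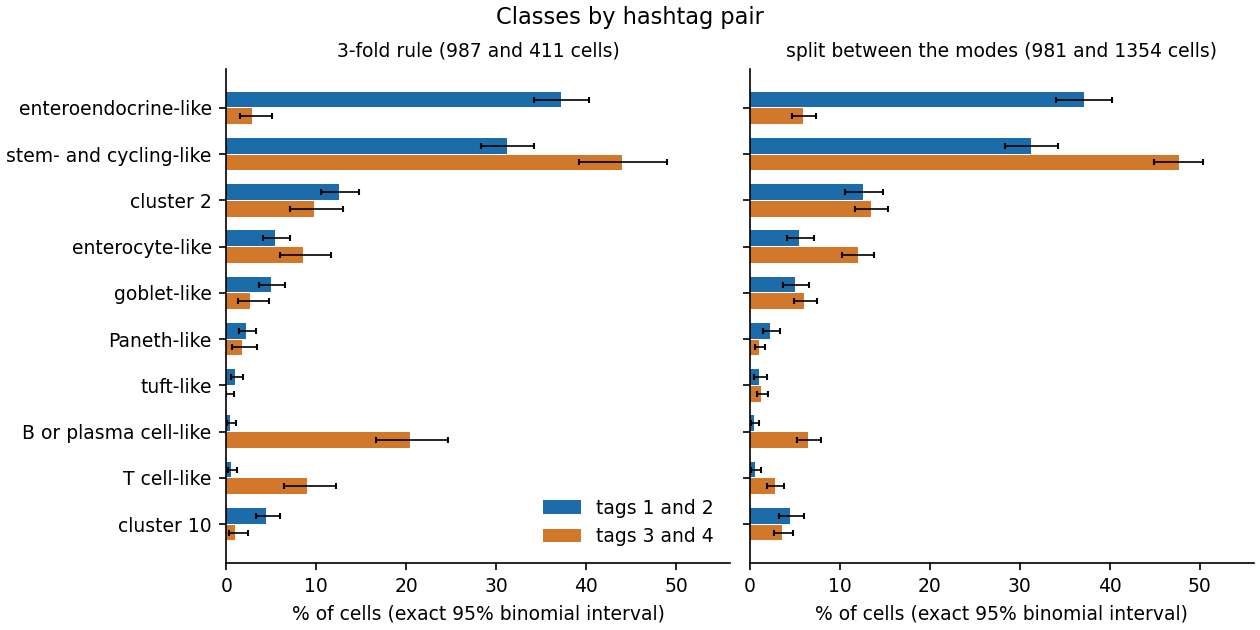
Percent of cells (horizontal axis) in each class for tags 1 and 2 (blue) and tags 3 and 4 (orange), with exact 95% binomial intervals, under the 3-fold rule (left) and the split between the modes (right). Enteroendocrine-like cells are 37.2% against 2.92% on the left and 37.1% against 5.91% on the right.

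Summed over all cells, tags 1 and 2 were higher in hormone and granule transcripts and tags 3 and 4 in lymphocyte transcripts. Levels are given as CPM, the UMIs of a gene per 1000000 UMIs summed over the cells compared, and ratios are log2 values with 10 CPM added to both sides. Gip (ENSMUSG00000014351), which encodes the incretin GIP, had 1966 CPM (1947 to 1985) in tags 1 and 2 and 26.3 (23.2 to 29.7) in tags 3 and 4, a log2 ratio of 5.77. Chga (ENSMUSG00000021194) had 2345 (2324 to 2366) against 179 (171 to 188), a log2 ratio of 3.64. The other 10 of the 12 genes named as highest were Ghrl (ghrelin, 5.11), Gcg (glucagon-family peptides, 4.79), Cck (cholecystokinin, 3.997), Chgb (another granin, 3.73), Afp (3.57), Tac1 (the substance P precursor, 3.49), the reporter YFP (3.42), Reg4 (3.398), Tph1 (the rate-limiting enzyme of serotonin synthesis in the gut, 3.26) and Sct (secretin, 3.24). YFP had 149 CPM (144 to 154) against 4.87 (3.58 to 6.47).

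The 12 genes named as lowest in tags 1 and 2 are expressed in lymphocytes, whose share was higher in tags 3 and 4. Cd79a (ENSMUSG00000003379), a subunit of the B cell receptor, had 1.67 CPM (1.16 to 2.32) against 57.3 (52.6 to 62.3), a log2 ratio of -2.53. Ccl5 (-2.96) and Gzma (-2.49) encode a chemokine and a granzyme of cytotoxic lymphocytes. Cd52 (-2.89), Ptprc (the common leukocyte antigen, -2.04), Ighm (the IgM heavy chain, -1.89), Ebf1 (a B cell transcription factor, -1.86), Srgn (-2.30), Coro1a (-2.03), Arhgdib (-1.90), Mef2c (-1.76) and Rgs1 (-1.67) followed. Without the B, plasma and T cell-like clusters, Cd79a, Cd52 and Ptprc turned to 0.02, 0.02 and 0.03. With the split at the valley the same 12 higher genes ranged from 2.44 (Sct) to 3.01 (YFP), and Gip was 2.81. When genes were named anew at that split, the highest was Sst (3.05) and the lowest Igkc (-1.90). The 12 lowest named there also included Zg16 (-1.89), Reg1 (-1.48) and Fabp1 (-1.04), beside Cd52 (-1.62) and Cd79a (-1.34).

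Among gene groups fixed in advance, the 3 enteroendocrine groups were higher in tags 1 and 2 in nearly all members. Hormone and amine synthesis genes were above in 13 of 13 measured members (median log2 ratio 3.24), dense-core vesicle and exocytosis genes in 18 of 18 (median 2.44; Pcsk1, a prohormone convertase, 193 against 17.9 CPM), and enteroendocrine transcription factors in 19 of 20 (median 1.59). Of these factors Neurod1 had a log2 ratio of 2.77, Fev 2.59 and Nkx2-2 2.30, while Sox4 had 0.15. The 10 dissociation and stress genes were all above (median 0.87; Jun 0.65, Fos 0.99, Ier2 0.33). Both transgene transcripts were above, with tdTomato at 88.1 against 16.7 CPM (1.88). Antimicrobial Reg3 genes were below in 4 of 4 (median -0.96; Reg3b -1.42, Reg3g -1.38), and MHC class II genes in 7 of 7 (median -1.14; Cd74 590.3 against 1378 CPM), beside a B or plasma cell-like share of 0.405% against 20.4%. Stem-like markers were below in 9 of 10 (median -0.29; Olfm4 -0.28, Slc12a2 -0.33, Lgr5 -0.62) and cycling markers in 8 of 11 (median -0.20).

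Notch pathway genes divided into 4 above, 1 below and 4 with overlapping intervals (median -0.03; Hes1 -0.03, Hes6 0.31, Notch1 -0.23). Of 6 reported reserve stem cell genes, 1 was above, Hopx (0.69), and 5 overlapped, among them Bmi1 (0.22) and Lrig1 (-0.11). Of 3 measured fetal-like and regeneration genes, Ly6a was above (1.37) and Clu (0.02) and Anxa3 (-0.11) overlapped. These sums cover all cells. Within stem- and cycling-like cells, 0 of 5 measured reserve stem cell genes were above (median -0.11). No fetal-like gene had enough UMIs there to be measured. At the valley split, all 6 reserve stem cell genes, Hopx included, and all 3 measured fetal-like genes overlapped in this class. Ly6a was found in 52.7% of enteroendocrine-like cells of tags 1 and 2 at that split, and in 35% of those of tags 3 and 4.

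The next comparison followed the driver gene and the reporter through the classes. Chga was found in most enteroendocrine-like cells of both pairs. Its summed level in this class was higher in tags 1 and 2 at the valley split, as given below. YFP differed between the pairs in every epithelial class with UMIs in both. Thinned to 2000 UMIs, Chga was found in 88.0% of 351 enteroendocrine-like cells of tags 1 and 2 (84.2 to 91.2%; 16 shallower cells left out) and in 90.9% of 11 of tags 3 and 4 (58.7 to 99.8%; 1 left out). In stem- and cycling-like cells it was found in 4.90% of 306 (2.77 to 7.96%; 2 left out) and 5.14% of 175 (2.38 to 9.54%; 6 left out), and without thinning in 37.3% and 37.6% at median depths of 23863 and 27175 UMIs. B or plasma cell-like cells of tags 3 and 4, which should lack Chga, had it in 22.9% of 70 thinned cells (13.7 to 34.4%; 14 left out) and 31.0% without thinning, at a median of 2576 UMIs. These classes differ in depth, so thinning to 2000 UMIs keeps a larger part of the free RNA in the shallow B or plasma cell-like cells. This background therefore cannot decide whether stem- and cycling-like cells held Chga transcripts of their own. Unthinned values for enteroendocrine-like cells were 93.7% and 100% at medians of 11505 and 27819 UMIs.

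YFP in stem- and cycling-like cells reached 134 CPM (126 to 142) in tags 1 and 2 and 2.40 (1.28 to 4.10) in tags 3 and 4. At least 3 YFP UMIs were found in 88 of 308 of these cells (28.6%; 23.6 to 33.97%) against 0 of 181, for which the exact upper bound is 2.02%. With thinning, 15.4% and 0% had a YFP UMI, and without it 38.0% and 6.63%, beside 1.43% and 2.38% of the B or plasma cell-like cells of tags 3 and 4. In enteroendocrine-like cells, 48.5% (43.3 to 53.7%) against 16.7% (2 of 12; 2.09 to 48.4%) held at least 3, and in enterocyte-like cells 31.5% (19.5 to 45.6%) against 2.86% (1 of 35; 0.0723 to 14.9%). The Chga-linked tdTomato transcript was at 290.2 CPM (276 to 304) against 140.2 (103 to 187) in enteroendocrine-like cells, and at 6.72 (5.07 to 8.72) against 10.3 (7.81 to 13.4) in stem- and cycling-like cells.

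**Figure D3:**
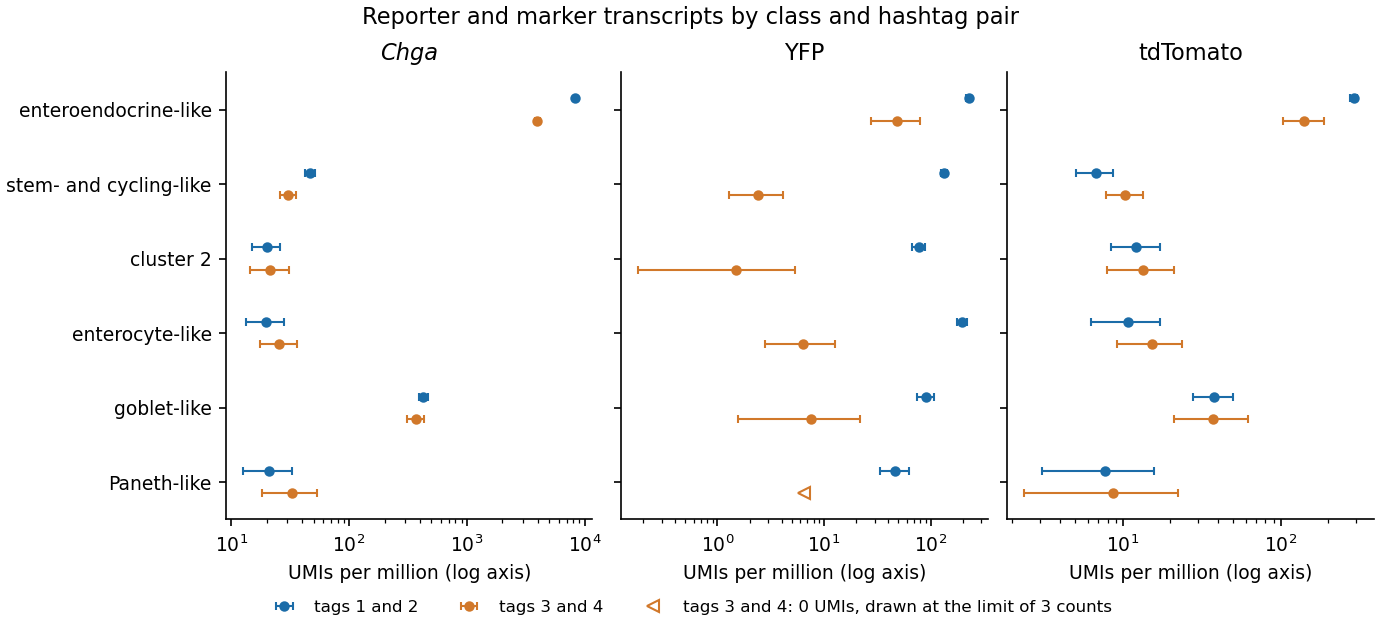
CPM (horizontal log axis) of Chga, YFP and tdTomato in 6 classes, for tags 1 and 2 (blue) and tags 3 and 4 (orange) under the 3-fold rule; bars are exact 95% Poisson intervals and the open triangle marks 0 UMIs, drawn at the limit of 3 counts. YFP in stem- and cycling-like cells is at 134 in tags 1 and 2 and 2.40 in tags 3 and 4, while tdTomato there is at 6.72 and 10.3.

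Within stem- and cycling-like cells (308 against 181), most genes were close between the pairs. Of 3835 genes with at least 500 UMIs, 99.8% lay within 1.5-fold. After YFP (3.54), the highest were the inducible HSP70 genes Hspa1a (110.3 CPM, 103 to 118, against 19.0, 15.5 to 23.1; log2 ratio 2.05) and Hspa1b (1.76), then Eif2s3y (ENSMUSG00000069049), a gene of the Y chromosome, with 13.4 (11.1 to 16.2) against 0.185 (0.00467 to 1.03), and Sst (somatostatin, 15.2 against 1.29; 1.16), for which 1 cell of tags 1 and 2 held 102 of their 127 UMIs. The lowest were the secreted antimicrobial lectins Reg3b (451, 436 to 465, against 1178, 1149.7 to 1208; log2 ratio -1.37) and Reg3g (-1.21), Pla2g5 (a secreted phospholipase, -0.75), Pdx1 (a transcription factor of the duodenum and pancreas, -0.69) and Stat3 (-0.60). MHC class II genes were below in 6 of 7 (median -0.40; Cd74 -0.35) and stem-like markers in 7 of 10 (median -0.15; Olfm4 -0.03, Slc12a2 -0.11, Lgr5 -0.28), while 9 of 11 cycling markers overlapped. Hormone and amine synthesis genes were above in 3 of 9 (median 0.26) and stress genes in 5 of 10 (median 0.17). Goblet markers were above in 5 of 9 and below in 1 (median 0.38), and enteroendocrine markers above in 4 of 11 (median 0.25). As with Sst, few cells weighed on the endocrine sums. Among 218 cells of tags 1 and 2 with at least 3 Xist UMIs and no Y-linked UMI, 1 held 96 of 176 Tac1 UMIs. The Reg3 difference depended on the tag rule. At 10-fold the 3 clusters of the class held 13, 10 and 1 cells of tags 3 and 4. There Reg3b was -0.16 and Reg3g -0.01, and at the valley split they were -0.71 and -0.82. Reg3b and Hspa1a also differed within tags 1 and 2. In 68 cells with Y-linked UMIs and at most 2 Xist UMIs they had 52.9 and 165 CPM. In the 218 cells named above they had 611 and 88.1. In 170 cells of that kind in tags 3 and 4 they had 1103 and 19.2. Leaving out the 6% of cells with the highest doublet scores, an alternative chosen after seeing the data, brought Sst to 0.23. Without the 5 cells of each pair with most UMIs of a gene, an alternative chosen after seeing the data, Sst was at 0.26, Reg3b at -1.71 and Reg3g at -1.15.

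Within the enteroendocrine-like class, the 3-fold rule left 12 cells in tags 3 and 4, under the minimum of 20, so the valley split was used (364 against 80 cells). Endocrine and stress transcripts were higher in tags 1 and 2, and transcripts of several other classes lower. Enteroendocrine markers were above in 16 of 16 (median 0.78), dense-core vesicle genes in 17 of 18 (median 0.81; Chga 8352 against 4269 CPM), hormone and amine genes in 11 of 13 (median 0.78; Gip 0.78, Cck 0.81) and enteroendocrine transcription factors in 14 of 20 (median 0.48; Neurod1 0.47, Fev 0.92, Sox4 -0.39). Cycling markers were below in 9 of 11 (median -0.73) and progenitor markers in 4 of 5 (median -0.57), among them Neurog3 (ENSMUSG00000044312), which specifies the endocrine lineage, at 47.9 CPM (42.4 to 53.9) against 119 (103 to 137), a log2 ratio of -1.16. Stem-like markers were below in 5 of 10 (median -0.38; Olfm4 1666 against 2439 CPM), goblet markers in 5 of 10 (median -0.39; Agr2 201 against 405 CPM) and MHC class II genes in 6 of 7 (median -0.69; Cd74 247 against 538 CPM), while stress genes were above in 9 of 10 (median 0.52; Fos 0.60). The 6% of cells with the highest doublet scores made up 14.6% of the class in tags 1 and 2 (53 cells; 11.1 to 18.6%) and 36.3% in tags 3 and 4 (29 cells; 25.8 to 47.8%). Of 2 clusters with leading enterochromaffin genes, cells led by Afp, Reg4 and Trpa1 were 26.6% of the class (22.2 to 31.5%) against 12.5% (6.16 to 21.8%), and cells led by Tac1 and Tph1 were 52.2% (46.9 to 57.4%) against 61.3% (49.7 to 71.9%). Peptide hormone cells led by Cck, Gcg and Gip were 21.2% (17.1 to 25.7%) against 26.3% (17.0 to 37.3%).

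Sst (ENSMUSG00000004366) showed the largest ratio of the class, 321 CPM (306 to 336) against 2.42 (0.659 to 6.19; 4 UMIs), a log2 ratio of 4.73, and was found in 7.97% and 5.00% of cells. Of its 1834 UMIs in tags 1 and 2, 5 cells held 1808. The other genes named as higher were YFP (1.46), Ly6a (1.39), Hspa1a (1.27), Pgc (the pepsinogen C gene, 1.26), Etv1 (1.24) and the Y-linked Ddx3y (1.43) and Eif2s3y (1.37). Those named as lower, besides Neurog3, were Reg3g (-2.07), S100a6 (-1.99), Reg3b (-1.85), Ooep (-1.82), Fyb (-1.23), Rnase1 (-1.13) and Epb42 (-1.10). Hspa1a had 25.4 CPM (18.3 to 34.3) in tags 3 and 4. In tags 1 and 2 it had 128 (112 to 147) in 107 cells with Y-linked UMIs and at most 2 Xist UMIs. In 166 cells with at least 3 Xist UMIs and no Y-linked UMI it had 42.0 (34.4 to 50.7). Without the 6% of cells with the highest doublet scores, Reg3b turned to 0.03, and Reg3g, Sst and Neurog3 were at -0.71, 3.66 and -1.83. In cells with Xist and without Y-linked UMIs, Reg3b was at -2.75, and thinning moved S100a6, Ooep and Epb42 to -3.01, -2.41 and -1.79. Several of these ratios rested on few cells. Without the 5 cells of each pair with most UMIs of the gene, Sst was at 0.55, Reg3g at -0.74, Reg3b at -0.11 and Epb42 at -0.04, and S100a6 (0.14), Fyb (0.12) and Ooep (0.10) turned, while Neurog3 was at -0.77 and YFP at 1.81.

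In cluster 2 and in enterocyte-like cells, YFP and Hspa1a were again among the genes named as higher, joined by gasdermin C genes. In cluster 2 (124 against 40 cells) these were YFP (77.6 CPM, 67.5 to 88.9, against 1.49, 0.180 to 5.37), Hspa1a (2.43), Gsdmc4 (2.01), the goblet gene Agr2 (1.74) and Hspa1b (1.55). Reg3g (-1.45), Duox2 (a peroxide-producing oxidase, -1.24), Reg3b (-0.97), Myadm (-0.96) and Myo10 (-0.88) were lower. As groups, goblet markers were above in 5 of 8 (median 0.83) and Paneth markers in 2 of 7 (median 0.57), the others overlapping. MHC class II genes were below in 4 of 7 (median -0.50) and above in 0. In enterocyte-like cells (54 against 35), YFP (3.65), Gsdmc2 (1.94), Gsdmc4 (1.76), Cyp3a11 (1.67) and Hspa1a (1.64) were higher. Olfm4 (-1.38), Ifitm3 (-1.34), the mitotic genes Hmmr (-1.27) and Birc5 (-1.17), and B3galt5 (-1.17) were lower. Enterocyte markers were above in 7 of 10 (median 0.53), stress genes in 9 of 10 (median 0.69), and cycling markers below in 8 of 11 (median -0.87). The marker differences depended on the tag rule: at the valley split (54 against 162 cells) enterocyte markers were below in 7 of 10 and above in none (median -0.27; Sis -0.65), and cycling markers below in 3 of 11 (median -0.25; Birc5 -0.47, Ube2c 0.17), with stress genes still above in 9 of 10 (median 0.30). There Gsdmc4 was at 0.59 in cluster 2 and Cyp3a11 at 0.52 in enterocyte-like cells; thinned to 2000 UMIs, Myo10 turned to 0.15 and Hspa1a of enterocyte-like cells was at 0.31. Without the 5 cells of each pair with most UMIs, Agr2 of cluster 2 was at 0.71, and in enterocyte-like cells Olfm4 was at 0.07, B3galt5 at -0.19 and Ifitm3 at -0.42, while 5 cells held all 87 Cyp3a11 UMIs of tags 1 and 2.

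Goblet-like cells were compared at the valley split (49 against 82 cells). Summed UMIs of Paneth cell products were higher in tags 1 and 2, mostly from few cells, with Lyz1 (lysozyme) at 1700.0 CPM (1629.9 to 1772) against 359 (335 to 385; log2 ratio 2.21), Defa26 (a defensin) at 1.78 and Itln1 (intelectin) at 1.61, as were Hspa1a (1.99) and Hspa1b (1.53). Goblet markers were below in 9 of 10 (median -0.39), led by Zg16 (2361 against 8401 CPM; -1.83), cycling markers were above in 7 of 11 (median 0.47; Top2a 0.78, Mki67 0.69), and stress genes were below in 7 of 10 and above in 2 (median -0.22). Afp (-3.18), Rgs2 (-1.51), Trpa1 (-1.17) and Gsta4 (-1.34) were also lower. The first 3 of these are leading genes of 1 of the enteroendocrine-like clusters, and 12 of the 131 goblet-like cells (9.16%; 4.82 to 15.5%) held at least 20 Chga UMIs. Without the 5 cells of each pair with most UMIs, Lyz1 was at 0.55, Defa26 at 0.16, Itln1 at 0.11, Afp at -0.27 and Trpa1 at -0.54, while Hspa1a was at 1.99 and Zg16 at -4.32.

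Sex-linked transcripts also divided by tag pair. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together gave 926 UMIs in tags 1 and 2 (44.1 CPM, 41.3 to 47.1) and 7 in tags 3 and 4 (0.725 CPM, 0.291 to 1.49), and were found in 31.3% (28.4 to 34.3%) against 1.46% (0.538 to 3.15%) of cells. Xist, the long noncoding RNA of the inactive X chromosome, was found in 76.2% (73.4 to 78.8%) against 95.1% (92.6 to 97.0%) of cells. Tag pair and sex-linked transcripts thus varied together, and values from cells with Xist and without Y-linked UMIs are among the alternatives tried.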

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

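No test was run in this part; the values below were looked at because they come from barcodes that the comparisons did not use. Of the 8913 barcodes that the authors left out, 7451 lay above the highest mitochondrial percentage of a kept cell, with a median of 24.8% mitochondrial UMIs and 3128 UMIs. Among them 1.15% (86 barcodes; exact 95% interval 0.924 to 1.42%) held at least 20 Chga UMIs and 1.503% (112 barcodes; 1.24 to 1.81%) at least 3 YFP UMIs. A further 937 left-out barcodes lay within the UMI, gene and mitochondrial limits of the kept cells, with a median of 3579 UMIs. Among these 10.0% (94 barcodes; 8.18 to 12.1%) held at least 20 Chga UMIs and 8.11% (76 barcodes; 6.44 to 10.0%) at least 3 YFP UMIs. In kept cells, with a median of 19078 UMIs, these shares were 15.7% (14.2 to 17.2%) and 14.9% (13.5 to 16.5%). Fewer barcodes reach a fixed number of UMIs at lower depth, so these shares do not compare levels. Chga was at 1344 CPM (1315 to 1374) in the 937 barcodes and 1136 (1127 to 1145.5) in kept cells. In the 7451 barcodes it was at 542 (534 to 550). YFP was at 107 (99.3 to 116), 66.5 (64.3 to 68.8) and 44.6 (42.4 to 46.8) CPM in the same order. No background share was estimated for left-out barcodes. No biological explanation was tested.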

How the results depend on the processing

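Alternatives chosen after seeing the data were the valley split, the limit to Xist cells without Y-linked UMIs, sums without lymphocyte clusters, clustering without YFP and tdTomato, leaving out the 6% of cells with the highest Scrublet scores, thinning to 10000 UMIs, and leaving out the 5 cells of each pair with most UMIs of a gene. Of 156 class shares, 133 stayed within the interval of the reported value, and the enteroendocrine-like share was higher in tags 1 and 2 in 13 of 13 alternatives. Of 592 log2 ratios of named genes, which do not include the last of these alternatives, 344 stayed within counting error, 243 moved and 5 turned sign. Scrublet's own threshold removed 2 cells and tests nothing. Except where stated, the cause was not tested.

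By construction, the tag rule sets the cells of tags 3 and 4: 120 at 10-fold and 1354 at the valley split, against 411. At 10-fold the shares of tags 3 and 4 were 0.833% goblet-like, 20% stem- and cycling-like and 3.33% enterocyte-like. At the valley split they were 5.91% enteroendocrine-like, 6.06% goblet-like, 1.26% tuft-like and 11.97% enterocyte-like.

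The stem- and cycling-like share of tags 1 and 2 was 43.3% at resolution 2, 35.8% with 15 components, 37.0% with 4000 variable genes, 44.4% by marker share, 35.4% without the class's markers, 35.6% with the stricter cell filter and 35.7% in Xist cells. That of tags 3 and 4 was 51.8% at resolution 2, 49.6% with 4000 variable genes and 54.3% by marker share. By marker share, Paneth-like cells were 6.28% and 4.62%, and tuft-like cells of tags 1 and 2 were 0.203%; with the stricter filter the latter were 1.90%. The enteroendocrine-like share of tags 1 and 2 was 30.3% in Xist cells and 33.6% without the highest doublet scores.

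The log2 ratio of Chga over all cells was 4.43 as a mean over cells, 4.50 thinned, 3.35 at 10-fold, 2.91 at the valley split, 3.42 in Xist cells and 4.68 without the highest doublet scores. Within enteroendocrine-like cells it was 1.22 as a mean over cells, 1.27 thinned, 1.03 in Xist cells and 1.26 without the highest doublet scores. YFP in stem- and cycling-like cells was 3.74 with the reduced total, 3.87 at 10-fold, 3.32 at the valley split and 3.70 in Xist cells.

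Signs turned for Cd52 (0.0205), Cd79a (0.0193) and Ptprc (0.0278) without the lymphocyte clusters, of which these genes are markers or leading genes. They also turned for Reg3b in enteroendocrine-like cells without the highest doublet scores (0.0287) and for Myo10 in cluster 2 thinned (0.15).

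Without the 5 highest cells, signs turned for S100a6 (0.14), Fyb (0.12) and Ooep (0.10) in enteroendocrine-like and Olfm4 (0.07) in enterocyte-like cells. With these cells left out, 0 of 24 genes named over all cells fell below 0.5 times their reported log2 ratio or turned. The counts were 7 of 16 in enteroendocrine-like, 5 of 10 in goblet-like, 4 of 10 in enterocyte-like, 1 of 10 in stem- and cycling-like cells and 1 of 10 in cluster 2.

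Depth limits the share of cells with a Chga UMI. Unthinned it was 93.7% and 100% of enteroendocrine-like cells and 37.3% and 37.6% of stem- and cycling-like cells of tags 1 and 2 and of tags 3 and 4. Thinned to 10000 UMIs it was 91.6% and 100%, and 18.3% and 14.7%.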

Other observations

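All tests in this part were chosen only after the result was seen. Within tags 1 and 2, the stem- and cycling-like cells with at least 3 YFP UMIs (88 cells; median 27202 UMIs) were compared with those without YFP (191 cells; median 22362 UMIs). Of 2203 genes with at least 500 UMIs, 99.5% lay within 1.5-fold. Stem-like markers had a median log2 ratio of 0.01, with 2 of 10 above and none below. Enteroendocrine markers were not higher in the cells with YFP, with 0 of 10 above, 3 below and a median of -0.33, or -0.09 without the 5 cells of each group with most UMIs of the gene. Chgb (-1.53), Chga (-1.10) and Tac1 (-0.97) were lower there, but in few cells: the share of cells with a UMI was 89.8% against 89.0% for Chgb and 34.1% against 38.2% for Chga, and 1 cell without YFP held 663 of 1712 Chgb, 100 of 232 Chga and 96 of 157 Tac1 UMIs. Without that cell, the only 1 with at least 20 Chga UMIs, the ratios were -0.87, -0.48 and -0.09, and without the 6% of cells with the highest doublet scores -0.37, -0.45 and -0.12; these alternatives were chosen after seeing the data. Likewise 1 cell with YFP held 102 of the 108 Sst UMIs behind a ratio of 2.04, which was -0.01 without the highest doublet scores. Tff3 (-1.06 and -1.04) and Mmp7 (-1.05 and -1.11) stayed lower, and Cyr61 (0.88 and 1.02), Atf3 (0.83 and 0.84) and Hbegf (0.76 and 0.69) higher, with all cells and without the highest doublet scores. Without the 5 highest cells Tff3 was at -0.58 and Mmp7 at -0.57. Reg3 genes were below in 3 of 3 (median -0.65), but 1 cell without YFP held 1089 of 2603 Reg3b UMIs and 1 held 531 of 1946 Reg3g UMIs; without the 5 highest cells of each group the median was -0.78. Goblet markers were below in 4 of 9 (median -0.38, then -0.06) and Paneth markers in 4 of 9 (-0.33, then -0.17). MHC class II genes were above in 4 of 7 (0.21, then 0.15), and of 10 stress genes 7 were above and 2 below (0.31, then 0.22). Cells with at least 3 YFP UMIs made up 29.0% of the stem-like cluster (21.4 to 37.6%) and 25.8% (17.1 to 36.2%) and 30.7% (21.3 to 41.4%) of the cycling clusters. Their share was 19.1% of 68 cells with Y-linked UMIs and at most 2 Xist UMIs (10.6 to 30.5%). It was 32.1% of 218 cells with at least 3 Xist UMIs and no Y-linked UMI (26.0 to 38.8%). The comparison by YFP did not account for these kinds of cell, which differ in Reg3b and Hspa1a as given below.

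Cells of tags 1 and 2 also differed by their sex-linked transcripts. In stem- and cycling-like cells, Reg3b had 52.9 CPM (43.2 to 64.1) in 68 cells with Y-linked UMIs and at most 2 Xist UMIs, and 611 (592 to 632) in 218 cells with at least 3 Xist UMIs and no Y-linked UMI. The latter kind of cell in tags 3 and 4 (170 cells) had 1103 (1075 to 1132). Here 5 cells held 46 of 103, 2280 of 3574 and 3098 of 5818 Reg3b UMIs. Hspa1a followed the opposite order, at 165 (148 to 184), 88.1 (80.7 to 96.1) and 19.2 (15.6 to 23.3), as did Hspa1b at 79.6, 46.7 and 9.67. YFP was at 109 (95.2 to 125), 147 (137 to 157) and 2.09 (1.04 to 3.73). Among enteroendocrine-like cells of tags 1 and 2, Cck had 10240.0 against 4926 CPM in 107 cells of the Y-linked kind and 166 of the Xist kind, with 8831 of 16674 and 6496 of 12669 UMIs in 5 cells, while Tac1 had 2491 against 2981 and Chga 7647 against 7549 CPM. Enteroendocrine-like cells were 43.1% of 248 cells (36.9 to 49.6%) and 29.5% of 563 cells (25.7 to 33.4%).

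YFP transcripts in stem- and cycling-like cells of tags 1 and 2 were weighed first. Free RNA would reach both pairs alike, since both shared 1 set of droplets, but YFP was 55.8 times higher in tags 1 and 2 (134 against 2.40 CPM), which argues against it. Doublets with enteroendocrine-like cells would bring Chga along, but cells with at least 3 YFP UMIs held 0.0370 Chga UMIs per YFP UMI against 36.6 in enteroendocrine-like cells, or 0.101% of that ratio. Descent from a cell that once expressed Chga, recombination in stem cells without lasting Chga expression, and a difference between the sorts stay open as untested hypotheses.

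Y-linked transcripts in tags 1 and 2 were weighed next. Free RNA would again reach both pairs, but the Y-linked genes together were 60.9 times higher in tags 1 and 2 (44.1 against 0.725 CPM). A single animal of either sex would give like shares of cells with Y-linked UMIs at low and at high Xist. The cells of tags 1 and 2 with at least 10000 UMIs numbered 709. Y-linked UMIs were found in 91.3% of 207 with at most 2 Xist UMIs and in 11.6% of 502 with more. The ratio was 7.90. Of the 709 cells, 189 held Y-linked UMIs and at most 2 Xist UMIs, and 444 held more Xist UMIs and no Y-linked UMI. These values argue against 1 animal as the source of tags 1 and 2. A candidate explanation is that tags 1 and 2 hold cells of more than 1 animal, 1 of them male, although the labels name 1 mouse. The values could also be shaped by doublets between such cells, which hold both kinds of transcript (58 of 709 cells, 8.18%), and that was not tested.

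Goblet-like and tuft-like cells with enteroendocrine transcripts were weighed last: at least 20 Chga UMIs were found in 12 of 131 goblet-like (9.16%) and 4 of 27 tuft-like cells (14.8%), against 0 of 216 enterocyte-like, 0 of 35 Paneth-like and 4 of 951 stem- and cycling-like cells (0.421%), the last with a median depth of 50664 UMIs against 22495 in their class. Doublets with enteroendocrine-like cells, most of which carry tags 1 and 2, would raise the counts of tags 1 and 2 on the other side of the split. Of 7 such goblet-like cells there, 6 (85.7%, 42.1 to 99.6%) held more of these counts than 90% of their class. Their median was 159 counts of tags 1 and 2 against 75 in the others, and 124 of tags 3 and 4 against 89. Median depth over both sides was 30417 UMIs against 22145. The values go with doublets, but a general rise of hashtag counts with depth was not set apart. Of 3 such tuft-like cells, 1 (33.3%, 0.840 to 90.6%) held more than 90% of its class. Their median depth was 9775.5 UMIs against 13727, with a median of 60 against 82.5 counts of tags 1 and 2. Doublets and a mixed secretory state cannot be told apart with so few tuft-like cells. A biological mixed state was not tested for either class.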
